A study of Mus musculus with 6 samples.

How the data were processed

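The RNA of iNKT cells sorted from the spleen was sequenced in 6 samples, 3 labelled WT and 3 labelled Gpx4 cKO. Per the labels' protocols, RNA was isolated from the sorted cells with a NucleoSpin RNA XS Micro kit and libraries were made with a QIAseq UPXome kit. The genome builds GRCm38 and mm10 are named in the submitters' processing notes. The aligner, the counting tool, the annotation release, the use of strand and of molecular identifiers, and how reads with several matching loci were assigned are not given in the sources used here.

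A single deposited table held 48709 genes with Ensembl identifiers for each of 6 libraries. Per the file headers, it gave whole read counts on exons per gene, the fraction of each gene's reads that fell on introns, RPKM values and exon lengths. The deposited counts are not normalized, and they were used for all levels and tests. The deposited fraction of intron reads was used with the exon count to recover the number of intron reads of each gene with at least 1 exon read. The deposited RPKM values are scaled by exon length and depth by the authors, and they are quoted for Gpx4 only. The table held 11 further columns of values per library, which were not used.

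The libraries are named in the table by a number from 18 to 23 and a pair of index sequences. None of these names occurs in a label, so 0 of the 6 libraries were matched to a genotype. Library order, depth and the level of Gpx4 were not used in place of a label. The comparison of Gpx4 cKO with WT planned before the data were examined, by edgeR's quasi-likelihood test with gene set tests, was therefore not run. In its place each library's values are given, with the range and median over libraries. Nothing in the labels says whether the samples came from separate animals.

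Levels were expressed as CPM, counts scaled to a library of 1000000 reads, on effective library sizes, from TMM factors computed in edgeR 4.0.16 under R 4.3.3 on the 9510 genes kept by filterByExpr with all libraries as 1 group. TMM factors ranged from 0.917 in library 21 to 1.05 in library 19. Shares of reads used all exon reads as the total. Poisson intervals were exact, shares of a library have exact binomial intervals, and shares of receptor segments have Wilson intervals, all at 95%. The limit for a count of 0 was 3 reads. Whether a gene differed between libraries by more than counting error was tested with a chi-square test of its counts against the effective library sizes, with 5 degrees of freedom, for genes with at least 200 reads in total. The p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The test says nothing about genotype, and with deep libraries it detects differences of small size. Reads are not independent molecules where copies made by PCR were counted, so these intervals and tests cover counting error only.

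Gene lists, 43 in all, were fixed before the data were examined: 28 for iNKT biology and GPX4 deletion, 13 for other cell types and 2 for RNA quality. Symbols were matched by name or through Ensembl identifiers, and 17 symbols stayed unmatched. Several genes carry older names in the table, such as Selt and Vimp for selenoproteins and Fth1_2 for the ferritin heavy chain. Counts of varying members were adjusted over all tested genes. Adjusted over the list alone, the count was 1 higher for ferroptosis defence, oxidative phosphorylation, apoptosis, and chaperones, and no other list's count changed.

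The rule for named genes was set before the data were examined. It took Gpx4, the changed genes with the largest log2 fold changes, and the list members with the smallest p. All but Gpx4 needed the genotype comparison, so the rule could not be applied. After the data were examined it was replaced by Gpx4, the 4 members of each iNKT list and the 3 members of each other list with the highest median CPM, and the 30 genes with the widest log2 range (prior count 2, mean of at least 20 CPM, predicted genes and pseudogenes left out). Some of those 30 are given as counts, and a few genes that the rule takes are not reported here. Other named genes are textbook markers or single features chosen after their values were seen.

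A gene was counted as in excess in a single library when its CPM there was over 8 times the highest other value plus 1, with at least 50 reads. Its exon fold was its CPM there plus 1, over the median CPM of the other libraries plus 1. The intron fold was computed alike, on intron reads scaled to each library's total of intron reads. The chi-square test and the rule for excess were tested on simulated counts for the 9042 tested genes, of which 200 were changed in 1 library. The test called 91% of 2-fold and 100% of 20-fold changes, and 15 unchanged genes. The rule found all 100 of the 20-fold changes and 0 other genes. The simulated counts held Poisson error alone. Every pair of deposited libraries differed by more than that (lowest chi-square per gene 10.5), so these rates need not carry over to the deposited counts. Computations used Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and numpy 2.4.6. Transcripts of GENCODE release M21 were aligned with blastn 2.17.0 where stated. Gpx4 has the same coordinates in that annotation as in the deposited table. Genes with near-identical copies, among them the Trav and Trbv segments, Hspa1a and Hspa1b, the globins, immunoglobulin segments and Lars2, are uncertain. Alternatives tried were RLE scaling, scaling without a filter and with a stricter filter of at least 5 CPM in 3 libraries, total counts without scaling, and leaving out each library in turn. After the data were examined, list ranges were also computed without the most abundant member, and for B cell markers without immunoglobulin genes.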

Results

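Splenic invariant natural killer T (iNKT) cells, T cells that recognise lipids on CD1d through a semi-invariant receptor, were sorted from mice and their RNA was sequenced. The labels describe 6 samples of cells in the resting state, 3 wild type (WT) and 3 with a conditional knockout of Gpx4 (Gpx4 cKO). Gpx4 encodes glutathione peroxidase 4, the selenoenzyme that reduces lipid hydroperoxides in membranes and restrains ferroptosis, an iron-dependent form of cell death. The question posed by the design was how the iNKT transcriptome differs between the genotypes. The deposited table holds 6 libraries, numbered 18 to 23, whose names appear in none of the labels. No library was therefore given a genotype, and no WT against Gpx4 cKO comparison was made. Each library is reported by its number, and values over the 6 libraries are given singly or as a range and median.

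Library depth differed 11.2-fold, or 5.28-fold without library 21. Total exon reads were 8020374 in library 18, 10122187 in library 19, 5432206 in library 20, 903524 in library 21, 5406110 in library 22 and 1916746 in library 23. A count of 0 allowed up to 0.282 CPM (exon reads scaled to a common library size) in library 19 and up to 3.62 CPM in library 21. At least 1 read was found for 11866 genes in library 21 and for 18777 genes in library 20. Depth alone did not set this number. Library 19, the deepest, held 15744 such genes, and library 22, close to library 20 in depth, held 15190. All 95% intervals and these limits cover counting error only.

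Gpx4, the targeted gene, was read in all 6 libraries and differed between them by more than counting error. It lies on chromosome 10 of GRCm38 at 80047166 to 80056439 on the plus strand (ENSMUSG00000075706), with 1724 bases of exon in the deposited table. Its level was 30.1 CPM (95% exact Poisson interval 26.5 to 34.1, 250 reads) in library 18 and 3.20 CPM (2.22 to 4.47, 34 reads) in library 19. Library 20 held 31.3 CPM (26.8 to 36.3, 172 reads) and library 21 held 14.5 CPM (7.48 to 25.3, 12 reads). In library 22 it was 29.0 CPM (24.6 to 33.9, 157 reads) and in library 23 it was 11.1 CPM (6.85 to 16.9, 21 reads). The highest value, in library 20, was 9.77 times the lowest, in library 19 (95% interval 6.73 to 14.6). Without library 19 the ratio of highest to lowest was 2.82. The authors' own values, in RPKM, a depth-scaled read count per kilobase of exon, were 8.30, 0.937, 7.51, 3.66, 8.27 and 2.93 in libraries 18 to 23. By that measure library 18 was highest, and libraries 18 and 22 lay above library 20. Reads on Gpx4 introns numbered 41, 30, 33, 0, 44 and 6 in libraries 18 to 23. The counts cover the whole gene, so reads from undeleted exons of a recombined allele would be counted with the rest.

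**Figure D1:**
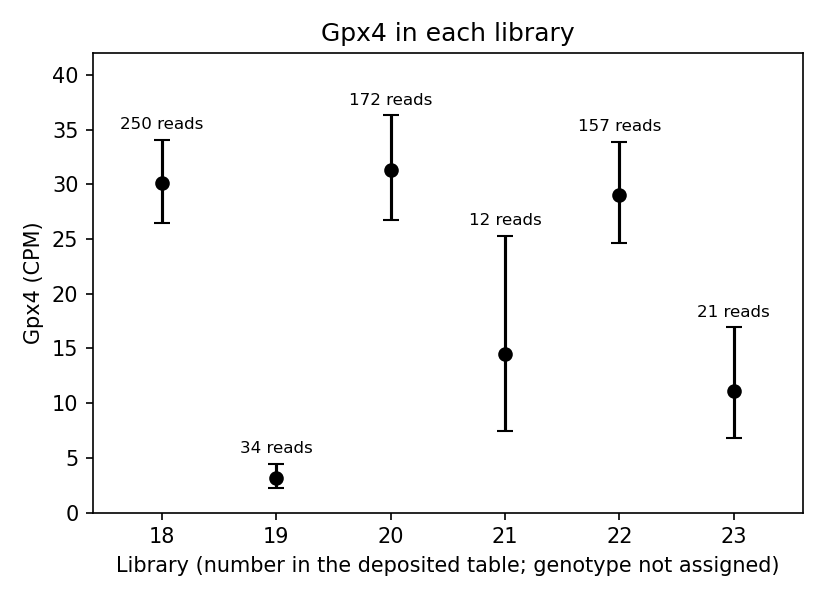
Gpx4 level in each library in CPM, with the number of exon reads above each point and 95% exact Poisson intervals as bars. The points lie between 3.20 CPM in library 19 and 31.3 CPM in library 20, and the interval of library 21, from 12 reads, spans 7.48 to 25.3 CPM.

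Transcripts of iNKT cells, several of which other T cells also express, were abundant in every library. Zbtb16, which encodes the transcription factor PLZF that directs the innate-like programme of these cells, ranged from 245 CPM in library 19 to 357 CPM in library 18. Cd3e, a chain of the T cell receptor complex, ranged from 764 to 924 CPM, and the receptor alpha constant gene Trac from 398 to 528 CPM. Il7r, the receptor for a survival cytokine, had a median of 1076 CPM, Cxcr6, a chemokine receptor of NKT cells, 1014 CPM, and the kinase gene Fyn 544 CPM. Of the 30 listed iNKT identity and development genes, 29 were in the table and 27 had a median of at least 1 CPM. The sum over this list varied 1.18-fold, from 6697 CPM in library 23 to 7931 CPM in library 22. All 25 members with enough reads for the test differed between libraries by more than counting error. Of all tested genes 71.6% did so, the share to set beside the counts given for each list. The test detects smaller differences in genes with more reads, so a list of abundant genes can exceed that share without a wide spread. Of the 25 members tested here, 22 stayed within a 2-fold range. So did 51 of 55 cytosolic ribosomal protein genes, all of which varied beyond counting error.

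Among receptor segments, that of the invariant alpha chain predominated. This segment, Trav11, took 67.2% to 76.7% of the reads on Trav segments (median 73.9%). In library 21, where 61 Trav reads were found, its share of 67.2% had a 95% Wilson interval of 54.7% to 77.7%. Among Trbv segments, Trbv29 took a median of 37.7% of reads, Trbv1 30.9%, Trbv13-1 10.3% and Trbv13-2 6.51%. Trbv1 showed the lowest share in library 21, 20.9% (Wilson interval 15.8% to 27.1%), and the highest in library 22, 32.5% (30.2% to 34.8%). Reads can be shared between near-identical V segments, so these shares are uncertain.

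Markers of the NKT1 subset, the interferon-producing branch, and of the NKT2 subset, the interleukin-4-producing branch, were both present. Tbx21, the T-bet gene of NKT1 cells, ranged from 59.0 CPM in library 23 to 160 CPM in library 18. Among the other NKT1 markers, Il2rb, a receptor chain for interleukins of the common gamma family, had a median of 885 CPM and was highest in library 19 at 1376 CPM. The chemokine gene Ccl5 had a median of 367 CPM, the transcriptional regulator gene Id2 914 CPM and Ms4a4b 444 CPM. Ifng was highest in library 20, at 152 CPM, and lowest in library 19, at 40.6 CPM. Klrk1, which encodes the activating receptor NKG2D, ranged from 65.9 CPM in library 23 to 306 CPM in library 20. Of 24 NKT1 markers, 19 were tested and all 19 varied beyond counting error, with list sums from 3619 CPM in library 23 to 5556 CPM in library 19.

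Gata3, the transcription factor gene shared with type 2 helper cells, ranged from 141 CPM in library 21 to 219 CPM in library 20. Cd4 had a median of 400 CPM, Lef1 339 CPM and Icos, a costimulatory receptor gene, 207 CPM. Other T cells also express these genes, so they do not single out NKT2 cells. Il4 was low in every library, from 7.53 to 25.3 CPM, and Il17rb ranged from 38.0 CPM in library 22 to 129 CPM in library 21. All 15 tested NKT2 markers, of 16 listed, varied beyond counting error, and the list sum ranged from 1932 to 2476 CPM. NKT17 markers were scarce. Ccr6, a chemokine receptor gene, ranged from 1.66 to 8.45 CPM, and no read of Il17a was found in any library. The sum over the 20 NKT17 markers, 1519 to 2230 CPM, came mainly from genes that other T cells also express. Cxcr6 (median 1014 CPM), Rora (445 CPM) and Maf (241 CPM) were its most abundant members, followed by Tmem176b at 37.4 CPM. All 9 tested members varied beyond counting error.

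**Figure D2:**
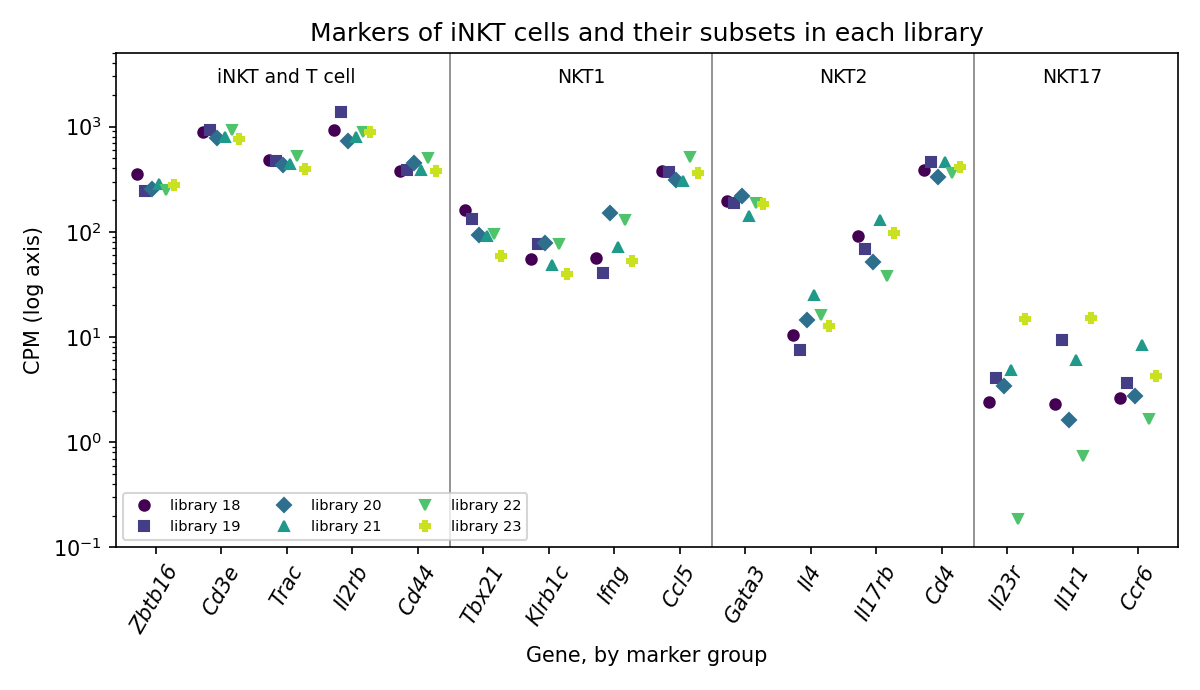
CPM, on a log axis, of markers of iNKT cells and of the NKT1, NKT2 and NKT17 subsets, with 1 point per library. Cd3e lies between 764 and 924 CPM and Ccr6 between 1.66 and 8.45 CPM. The points carry no error bars and values of 0 are not drawn.

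The sum over the 23 listed genes of ferroptosis defence, Gpx4 among them, ranged from 1246 CPM in library 19 to 1464 CPM in library 21, a 1.18-fold range. Without the ferritin heavy chain gene, its most abundant member, the sum ranged 1.23-fold, from 719 CPM in library 19 to 882 CPM in library 23. The most abundant members were the ferritin heavy chain gene, listed as Fth1_2 (median 570 CPM), Prdx6 (130 CPM), Nfe2l2 (127 CPM), which encodes the antioxidant regulator NRF2, and the desaturase gene Scd2 (123 CPM). Of 16 tested members, 14 varied beyond counting error and 9 stayed within a 2-fold range. Slc7a11, the cystine transporter gene, was at most 4.74 CPM, with no read in library 21. Aifm2, which encodes the GPX4-independent suppressor FSP1, ranged from 0.527 to 3.62 CPM. Values this low do not exceed the limit for a count of 0 in library 21, which is 3.62 CPM.

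Ferroptosis promotion and marker genes summed to 727 to 819 CPM, a 1.13-fold range. Acsl4, the enzyme gene that loads polyunsaturated fatty acids into membranes, had a median of 82.2 CPM and was highest in library 21 at 128 CPM. Sat1, a polyamine-degrading enzyme gene, had a median of 170 CPM and Ncoa4, the ferritinophagy receptor gene, 65.3 CPM. Vdac2, a mitochondrial channel gene, ranged from 111 to 124 CPM, a spread that counting error could give (adjusted p = 0.509, chi-square test). Chac1 and Ptgs2, transcripts often used as ferroptosis markers, were at 0 in 4 of the 6 libraries each. Of 16 tested members of this list, 13 varied beyond counting error.

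The 26 NRF2 target genes summed to 1497 CPM in library 19 and 1802 CPM in library 18, with Txnrd1 (median 238 CPM), Tkt (162 CPM) and Prdx1 (128 CPM) the most abundant after ferritin. Of 17 tested, 16 varied beyond counting error. The antioxidant enzyme list summed to 1382 CPM in library 20 and 2138 CPM in library 19, a 1.55-fold range set mainly by Txnip, which encodes a glucose-responsive thioredoxin inhibitor rather than an enzyme. Txnip ranged from 544 CPM in library 20 to 1285 CPM in library 19. Without it the list ranged 1.27-fold, from 839 CPM in library 20 to 1068 CPM in library 23. Sod1 ranged from 133 to 191 CPM. Catalase (Cat, adjusted p = 0.809) and Sod2 (adjusted p = 0.75) did not vary beyond counting error, and 15 of 18 tested members did. Selenoprotein and selenium-handling genes varied 1.08-fold in sum, from 1041 to 1122 CPM. Their leading members after Txnrd1 were Selt (155 CPM), Vimp (105 CPM) and Secisbp2 (84.2 CPM), and 14 of 20 tested varied beyond counting error. Iron-handling genes summed to 1669 to 1827 CPM, led after ferritin by Pcbp2 (median 263 CPM), Pcbp1 (107 CPM) and the iron importer gene Slc11a2 (82.3 CPM), and 15 of 22 tested varied beyond counting error.

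Cholesterol synthesis genes were low, and 13 of 18 tested varied beyond counting error. Their sum ranged from 353 CPM in library 19 to 537 CPM in library 21, and the regulator gene Srebf2 (median 42.4 CPM), Sc5d (41.5 CPM) and Stard4 (33.7 CPM) were among the most abundant. Fatty acid synthesis and desaturation genes summed to 1073 to 1261 CPM, with Acly (median 193 CPM), Acsl5 (131 CPM) and Tecr (102 CPM) prominent and 14 of 17 varying. Fatty acid oxidation genes summed to 819 to 997 CPM, with 14 of 20 varying. Hadha (median 150 CPM), Hadhb (124 CPM) and Hadh (72.2 CPM) led this list together with Acadl (77.0 CPM), whose spread counting error could give (adjusted p = 0.215).

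Glycolysis genes summed to 2490 to 2785 CPM, a 1.12-fold range, and 14 of 18 tested varied beyond counting error. Pkm had a median of 486 CPM, Eno1 311 CPM, Gapdh 248 CPM and Ldha 225 CPM. Nuclear genes of oxidative phosphorylation ranged from 3551 CPM in library 19 to 4308 CPM in library 18, with 45 of 51 tested varying, and Atp5b (320 CPM), Sdha (254 CPM), Cox6c (236 CPM) and Atp5a1 (233 CPM) led the list. The 13 mitochondrially encoded protein genes all varied and ranged further, from 32011 CPM in library 19 to 54378 CPM in library 21. Among these, mt-Co1 had a median of 11967 CPM, mt-Nd5 4163 CPM, mt-Atp6 3957 CPM and mt-Cytb 3902 CPM.

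Early-response genes of T cell activation ranged 2.53-fold in sum, or 1.58-fold without library 19. They were lowest in library 19 (3091 CPM) and library 18 (4963 CPM), and the other 4 libraries held 6912 to 7824 CPM. Sums of erythroid markers (9.16 CPM in library 18 and 14.5 CPM in library 19) and of the B cell list (1048 and 2012 CPM, mostly Igkc) were also lowest in these libraries. Fos, an AP-1 transcription factor gene, was 405 CPM in library 18, 103 CPM in library 19, 829 CPM in library 20, 807 CPM in library 21, 994 CPM in library 22 and 943 CPM in library 23. Jun ranged from 119 CPM in library 19 to 943 CPM in library 23, the phosphatase gene Dusp1 from 419 to 1156 CPM, and the NF-kappaB inhibitor gene Tnfaip3 from 430 to 1651 CPM. All 26 tested members varied beyond counting error. Chaperone and unfolded protein response genes ranged from 7685 CPM in library 19 to 14113 CPM in library 23, with 26 of 27 tested varying. Hspa8 (median 2927 CPM), Hsp90ab1 (1467 CPM), Hspa5 (1172 CPM) and Hsp90b1 (835 CPM) were the most abundant. The heat-inducible Hspa1b was at 4.24 CPM in library 19, 27.3 CPM in library 18 and 876 CPM in library 23. Its reads can be shared with the near-identical Hspa1a.

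The 29 genes of the integrated stress response under ATF4 summed to 1032 CPM in library 19 and 1472 CPM in library 23. Ppp1r15a, which reverses the translational block, ranged from 128 CPM in library 19 to 472 CPM in library 20. Atf4 ranged from 114 to 206 CPM, Slc3a2 had a median of 116 CPM and Wars 120 CPM, and 15 of 18 tested members varied. T cell receptor signalling and costimulation genes summed to 7186 to 9447 CPM, with Ptprc (median 2318 CPM), Plcg1 (581 CPM), Rasgrp1 (539 CPM) and Cd28 (536 CPM) at the top and 21 of 25 varying. Plcg1 was 1694 CPM in library 21 and at most 610 CPM elsewhere. Cytokine receptor and JAK-STAT genes summed to 7548 to 8665 CPM, 27 of 29 varying, with Jak1 at a median of 1003 CPM.

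Effector cytokine and cytotoxic genes summed to 1127 to 1525 CPM, and 13 of 14 tested varied beyond counting error. Ltb had a median of 337 CPM, Tnfsf10 127 CPM and Fasl 89.9 CPM, all ligands of the tumour necrosis factor family. Gzmb, which encodes granzyme B, was 74.8 CPM in library 21, 72.2 CPM in library 23 and at most 15.9 CPM in the other 4. Inhibitory receptor and exhaustion genes summed to 603 to 821 CPM, with 12 of 13 varying. Cd160 (median 124 CPM), Entpd1 (118 CPM), Cd5 (86.5 CPM) and Prdm1 (63.6 CPM) led, Pdcd1 ranged from 21.8 to 49.1 CPM, and Lag3 was at 0 in 3 libraries. Naive and circulating T cell genes summed to 3335 CPM in library 19 and 4252 CPM in library 18, 16 of 17 varying, led by Il7r, Satb1 (860 CPM), Lef1 and Foxp1 (299 CPM).

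Cell cycle genes were highest in library 23 (2983 CPM) and library 21 (2599 CPM) and lay between 1435 and 1753 CPM in the other 4 libraries. Mki67, a proliferation marker, was 201, 250, 171, 392, 177 and 558 CPM in libraries 18 to 23, and Top2a ranged from 76.0 to 303 CPM. Hmgb2 had a median of 431 CPM. Pcna, a replication clamp gene, ranged from 155 to 178 CPM and did not vary beyond counting error (adjusted p = 0.444), while 25 of 26 tested members of the list did. Libraries 21 and 23 were also the shallowest. They held the highest mitochondrial shares of exon reads (4.99% and 4.15%) and the lowest shares of the gene Lars2 (1.88% and 1.68%).

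Interferon response genes summed to 2660 to 3303 CPM, with Igtp (median 233 CPM), Ddx58 (224 CPM) and Zbp1 (207 CPM) among the most abundant, and 26 of 31 tested varied. Apoptosis and p53 target genes summed to 2019 to 2213 CPM, a 1.10-fold range, with 21 of 23 varying. Bcl2, an anti-apoptotic gene, ranged from 186 CPM in library 18 to 384 CPM in library 23, Sesn1 from 166 CPM in library 23 to 332 CPM in library 19, and Mcl1 and Trp53inp1 had medians of 218 and 228 CPM. Pyroptosis and necroptosis genes summed to 887 to 1022 CPM, and 7 of 11 tested varied. In this list the deubiquitinase gene Cyld was the most abundant (median 465 CPM), followed by Zbp1, Aim2 (73.6 CPM) and Ripk1 (64.0 CPM).

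Markers of cells other than iNKT cells ranged from absent to abundant. Plasma cell markers summed to 1033 CPM in library 18, 3469 CPM in library 19, 5012 CPM in library 20, 6376 CPM in library 21, 6510 CPM in library 22 and 8155 CPM in library 23. Their range was 7.89-fold, and 2.35-fold without library 18. Igha, the constant gene of the immunoglobulin A heavy chain and the most abundant member, ranged from 686 to 6234 CPM. Without Igha the list ranged 12.1-fold, from 347 CPM in library 18 to 4187 CPM in library 22. The joining chain gene Jchain ranged from 150 to 1185 CPM. Igkc, the kappa light chain gene, was lowest in library 18, at 605 CPM, and between 1735 and 4505 CPM in the other libraries. B cell markers as a list, mostly Igkc, ranged 5.10-fold, or 2.65-fold without library 18. Its 16 members that are not immunoglobulin genes ranged 3.15-fold, from 44.1 CPM in library 19 to 139 CPM in library 21. Cd79a, Cd79b and Ms4a1 together were at 24.3, 13.8, 40.5, 24.1, 39.3 and 21.6 CPM in libraries 18 to 23. Ighm had a median of 586 CPM and Iglc2 17.96 CPM, while Cd79a, a chain of the B cell receptor complex, was at most 12.7 CPM. All 10 tested members of each of these lists varied beyond counting error. Immunoglobulin genes took 0.217% of reads in library 18 and 1.45% in library 23 (exact binomial intervals 0.213% to 0.220% and 1.43% to 1.47%), a 6.70-fold range that was 2.27-fold without library 18.

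Erythroid markers ranged 52.5-fold in sum, from 9.16 CPM in library 18 to 481 CPM in library 23, and all 4 tested varied. The range was 17.3-fold without library 23 and 33.2-fold without library 18. The beta-globin gene Hbb-bs was 2.65, 2.35, 56.9, 47.1, 74.9 and 162 CPM in libraries 18 to 23, Hbb-bt had a median of 14.1 CPM, and Car2, a carbonic anhydrase gene, ranged from 1.45 to 131 CPM. Neutrophil markers summed to 14.2 to 97.5 CPM, nearly all from Mmp9 (median 49.1 CPM), the 1 member tested, with Mpo and Cxcr2 at medians of 1.44 and 0.186 CPM. Without Mmp9 the neutrophil list held 0.282 CPM in library 19 and 6.73 CPM in library 20, a 23.8-fold range. The value of library 19 equals the limit for a count of 0 there, so the size of this range is uncertain. The granule genes S100a8 and Ltf had no read. Macrophage and monocyte markers summed to 524 to 710 CPM, mostly Ccr2 (median 457 CPM) and Ctss (84.5 CPM), which T cells also express, and Vcam1 was at 3.45 CPM. Both tested members varied. Dendritic cell and MHC class II genes summed to 199 to 352 CPM, led by Ccr9 (median 122 CPM), Cd74 (50.2 CPM) and H2-Ab1 (11.7 CPM), all 4 tested varying. Without Ccr9, which T cells also express, the sum ranged 3.25-fold instead of 1.77-fold, from 55.6 CPM in library 19 to 181 CPM in library 21.

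**Figure D3:**
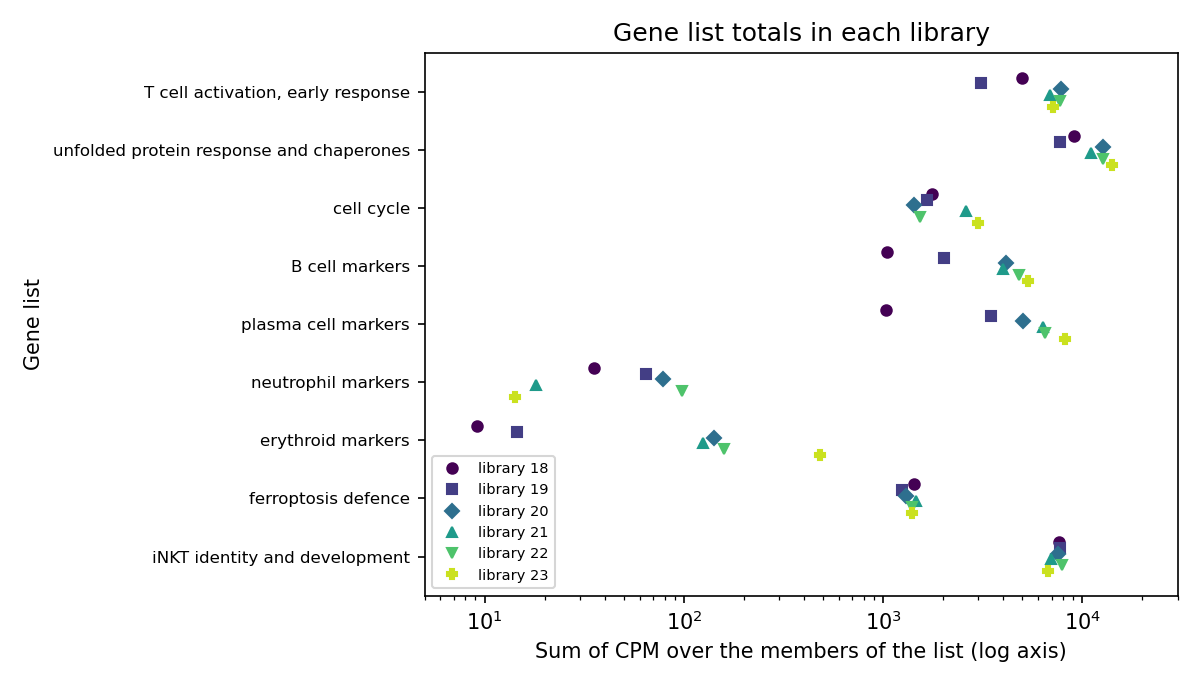
Sum of CPM over the members of 9 gene lists, on a log axis, with 1 point per library and no error bars. Erythroid markers spread from 9.16 CPM in library 18 to 481 CPM in library 23, and iNKT identity genes lie between 6697 and 7931 CPM.

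Conventional natural killer cell markers were low, at 61.7 to 115 CPM in sum, led by Itga2 (median 13.4 CPM), Irf8 (12.2 CPM) and Prf1 (11.2 CPM), 3 of 4 tested varying. Cd8a was at 0 in 5 libraries, with 1 read in library 22. The CD8 T cell list, 81.0 to 226 CPM in sum (2.79-fold, or 1.83-fold without library 19), came mainly from Ly6c2 (median 117 CPM), followed by Cd7 (19.8 CPM) and Eomes (1.47 CPM), both tested members varying. Regulatory T cell markers summed to 678 to 795 CPM and all 8 tested varied. They came from Ikzf2 (median 262 CPM), Il2ra (244 CPM) and Tnfrsf18 (149 CPM), whereas Foxp3, which specifies this lineage, ranged from 6.63 to 12.1 CPM. Gamma delta T cell genes summed to 348 to 437 CPM, with Trgv2 (109 CPM), Tcrg-C4 (78.1 CPM) and Tcrg-C1 (73.4 CPM) at the top, 3 of 6 varying, and Trdc at a median of 4.46 CPM. Platelet markers summed to 4.43 to 46.4 CPM (10.5-fold, 5.18-fold without library 23 and 6.54-fold without library 22) with none read deeply enough for the test, and Tubb1, Clec1b and Itga2b had medians of 4.20, 2.99 and 2.02 CPM. Stromal and endothelial genes summed to 92.2 to 130 CPM, nearly all from Pecam1 (median 104 CPM), the 1 member tested, which varied, with Pdgfrb and Igfbp7 at 0.998 and 0.599 CPM. Without Pecam1 that list ranged 8.93-fold instead of 1.41-fold, from 1.51 CPM in library 19 to 13.5 CPM in library 20. Thymocyte genes summed to 223 to 297 CPM, mainly from Themis (median 243 CPM) and Cd1d1 (20.9 CPM), both tested members varying, and Rag1, a recombinase gene of immature thymocytes, was at most 2.41 CPM.

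Measures of RNA quality also differed between libraries. Mitochondrial genes took 3.36% of exon reads in library 19 and 4.99% in library 21 (exact binomial interval 4.94% to 5.03%), with a median of 3.61%. Cytosolic ribosomal protein genes ranged from 39148 CPM in library 19 to 54886 CPM in library 18, all 55 varying, with Rpl4, Rpl13 and Rpl5 at medians of 2552, 2436 and 2395 CPM. The nuclear-retained RNAs summed to 3962 CPM in library 23 and 6140 CPM in library 18, led by Malat1 (median 4796 CPM), Gas5 (204 CPM) and Neat1 (148 CPM), all 3 tested varying. Introns took 45.5% to 50.6% of gene reads. The gene with the most reads was Lars2, a mitochondrial leucyl-tRNA synthetase gene, at 1.68% to 2.84% of exon reads, and its count is uncertain, since how reads matching several loci were assigned is not known. Xist, expressed from the inactive X chromosome, ranged from 2163 to 2605 CPM, and the Y-linked Ddx3y was at most 1.21 CPM, in library 21.

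Of 22065 genes with a read, 9042 had the 200 reads the test needed, and 6473 of these (71.6%) differed between libraries by more than counting error at an adjusted p under 0.05. This test compares libraries, not genotypes. Of the 6466 genes with a mean of at least 20 CPM, 5569 (86.1%) stayed within a 2-fold range, 897 did not, and the median ratio of highest to lowest library was 1.45. Of the 897 genes, 104 ranged over 8-fold or were at 0 in a library. Without library 21 these numbers were 482 and 55. Correlations across genes, which are not independent replicates, ran from 0.895 between libraries 19 and 21 to 0.978 between libraries 20 and 22. No pair of libraries agreed within sampling noise, since the lowest chi-square per gene over all pairs was 10.5, between libraries 20 and 22, and 15.7 without library 20.

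Of the 30 named genes with the widest range, 15 were highest in library 21, 9 in library 23, 5 in library 22 and 1 in library 19. Immunoglobulin genes made up 9 of them. Ighg1 was at 809 CPM in library 21 and had no read in libraries 18 and 19, and Ighg2c was at 2159 CPM in library 22 and 7.35 CPM in library 18. Cxcl10, an interferon-induced chemokine gene, was at 409 CPM in library 21 and at most 9.76 CPM in the other libraries. Gramd3 was at 17017 CPM in library 21 and at most 583 CPM elsewhere. Both are among 34 genes in excess in library 21 alone, and their intron reads were in smaller excess. Folds were taken over the median of the other libraries, with 1 added to both values. They were 60.3 for exon and 3.22 for intron reads of Cxcl10, and 39.4 and 3.05 for Gramd3. The interferon response list in library 21, at 2905 CPM, lay inside the range of the other libraries. Cd9, a tetraspanin gene, was at 1585 CPM in library 23 and at most 39.8 CPM elsewhere, and the kinase gene Syk at 589 CPM in library 23 and at most 15.8 CPM elsewhere. Their exon folds were 80.4 and 55.5, and their intron folds 1.36 and 4.72.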

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

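The genotype comparison was not run, because no library was matched to a label, and so neither were the other ways of running it: DESeq2, voom with sample weights, camera and fry on the lists, and a size threshold. No paired analysis was possible because the replicate numbers stand in the labels, and no library was matched to a label. Scaling by total counts was chosen after the data were seen; the other alternatives of scaling, filter and libraries were planned before, for the genotype comparison, and applied here to the values per library. Under RLE scaling, scaling without a filter or with a stricter filter, and total counts, the median of Gpx4 stayed between 21.2 and 21.7 CPM and its ratio of highest to lowest library between 9.37 and 9.81. Leaving out 1 library at a time, the median ranged from 14.5 to 29.0 CPM and the ratio from 2.82 to 9.77. The ratio of 2.82 came without library 19, which holds the lowest value. The count of genes that varied beyond counting error, 6473, became 6465 to 6646 under the other scalings and 5080 to 6155 with 1 library left out, where fewer libraries and reads enter the test. The median mitochondrial share stayed between 3.60% and 3.64%, and the median Trav11 share between 72.2% and 75.6%. Under the other scalings and filters, the median sum of each of the 43 lists moved by less than the SD over libraries. Leaving out 1 library cannot move a median of 6 values by the SD, so that comparison could not show a change. The ratio of highest to lowest library for a list left its 95% counting interval in 0 lists under RLE scaling and the stricter filter, 16 without a filter and 23 under total counts, at 0.874 to 1.14 times its value. Selenoprotein genes went from 1.08-fold to 1.19-fold and iron-handling genes from 1.09-fold to 1.18-fold under total counts. Without its most abundant member, chosen after the data were seen, the range of a list moved by over 1.5 times for 4 lists: plasma cell, neutrophil, dendritic cell, and stromal and endothelial markers. Without 1 library it did so for 6 lists, as stated with each. Depth limits library 21 most: its Gpx4 value rests on 12 reads, and genes under 3.62 CPM may go unread there.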

Other observations

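All tests in this part were chosen after the results were seen. The values of Gpx4 lay close together in libraries 18, 20 and 22, at 30.1, 31.3 and 29.0 CPM, and lower in libraries 19, 21 and 23, at 3.20, 14.5 and 11.1 CPM. No genotype was read from these values. Other genes parted the libraries differently. Hspa1a, an inducible heat shock gene, was 14.8, 0.565, 363, 122, 333 and 506 CPM in libraries 18 to 23, and Nr4a1, an early target of receptor signalling, was 24.7, 4.43, 44.9, 76.0, 38.9 and 50.1 CPM. Klf2, a regulator of T cell trafficking, was 35.9, 8.38, 54.5, 66.4, 46.9 and 67.5 CPM. Cpt1a, the entry enzyme gene of mitochondrial fatty acid oxidation, was highest in library 19, at 92.4 CPM, and lowest in library 20, at 29.8 CPM. Il23r, a receptor gene of NKT17 cells, was 14.8 CPM in library 23 and at most 4.83 CPM elsewhere. On the first principal component of log2 CPM, with 43.3% of the variance, library 21 lay at 38.8 and the others between -13.3 and -1.42.

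In library 21, the shallowest, 34 genes were in excess over every other library and took 6.49% of its reads. They include Bola2 (3351 CPM, against at most 26.9 CPM elsewhere), Rraga, Phb, Ncaph2, Apaf1, Zmiz1, Cxcl10 and Gramd3. The median excess over the other libraries was 22.8-fold for exon reads and 2.36-fold for intron reads of the same genes, and the intron fold was over 4 in 8 of the 34, which argues against higher transcription of whole genes as the sole source. Library 23 held 7 such genes (0.912% of its reads), with medians of 23.1-fold and 2.34-fold, library 22 held 3, all immunoglobulin genes (23.0-fold and 14.0-fold), library 19 held 1 and libraries 18 and 20 held 0. Uneven amplification of single fragments from little RNA may fit the values of libraries 21 and 23. It stays open there, since positions of reads within genes were not analysed here. In library 22 the intron reads of all 3 genes were in excess too, each over 4-fold. No other explanation was tested.

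Immunoglobulin reads differed 6.70-fold in share between libraries, and 2.27-fold without library 18. If B cells were the sole source, Igkc reads per read of Cd79a, Cd79b and Ms4a1 should be alike, and this ratio ranged 8.38-fold (95% interval 5.98 to 11.7), from 24.9 in library 18 to 208 in library 23. Without library 18 it still ranged 2.65-fold (1.90 to 3.70), beyond counting error. That interval reaches below the 2-fold set as the bound, so the spread of this ratio alone does not decide. Reads of Jchain, a plasma cell marker, numbered 1241, 5095, 4814, 791, 4110 and 2247 in libraries 18 to 23. Those of Cd79a, Cd79b and Ms4a1 together numbered 202, 147, 223, 20, 213 and 41. Jchain exceeded them in every library, which argues against B cells as the sole source. For antibody-secreting cells, Mzb1 reads per Jchain read ranged 8.09-fold (3.27 to 20.04), but 2.29-fold (0.879 to 5.98) without library 22. Mzb1 had 4, 26, 13, 2, 74 and 5 reads in libraries 18 to 23, too few in several of them to show a ratio within 2-fold. The ratio therefore cannot decide, and antibody-secreting cells stay open as the sole source. Igkc per Jchain read ranged 1.55-fold, or 1.17-fold (1.06 to 1.30) without library 22. The kappa variable segment with the most reads was Igkv12-44 in libraries 18, 21 and 22, Igkv4-59 in library 19 (24.5% of Igkv reads), Igkv8-30 in library 20 and Igkv6-25 in library 23; free RNA and differences between mice were not tested.

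Lars2 held the most reads of all genes, with a median of 24188 CPM. The longest alignment of its main transcript to the mitochondrial ribosomal RNAs was 27 bases. The least set for such reads to be assigned to it was 50 bases, which argues against that source for this transcript. Other transcripts of the gene were not aligned. Nuclear ribosomal RNA was not tested, and it stays open with the gene's own expression.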
